A study of Drosophila melanogaster with 4 samples.

How the data were processed

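Whole adult female flies were profiled by RNA sequencing in 4 groups of 1 library each: wild type and kdm5 mutant, each with and without paraquat. Libraries were made with poly-A selection by an Illumina TruSeq kit from total RNA of flies extracted in groups of 5, per the labels' protocols. The submitters' processing notes name Cufflinks and the genome build dm3. The aligner, its settings, the annotation release and whether counting used strand are not given in the sources used here.

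Each deposited table holds, for every FlyBase gene ID, a count of uniquely mapped reads, a length, a coverage and an RPKM value, per the file headers. The read counts are whole numbers and sum exactly to the total that the file headers give for the library. The deposited RPKM values equal the reads divided by the deposited length and by that total, on the usual RPKM scale, with a largest relative gap of 5.13e-07. The deposited length was within 5% of the whole gene span, introns included, for 92.3% of 7362 genes with introns, and within 5% of the summed exons for 0.992%. RPKM therefore understates the level of genes with long introns, while a ratio of RPKM of the same gene between libraries is not affected. The differences of log2(RPKM + 1) and the minimum RPKM used below are affected: such genes show smaller differences and reach the minimum less often. The coverage column, per the file headers, is the percent of that length covered by reads. The smallest count listed is 1, and the tables leave out 834, 665, 766 and 787 of the 12073 gene IDs seen in any library, which were taken as 0 reads, although a row could be missing for another reason. Symbols from the reference table matched 11667 of the IDs, and 406 IDs without one held 5.80% to 6.39% of reads. Gene positions are from the BDGP6 annotation, a later build than the one in the submitters' notes, and the files themselves carry no coordinates.

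The mitochondrial large ribosomal RNA took 9.12%, 11.5%, 10.4% and 12.9% of reads in wild type control, wild type paraquat, mutant control and mutant paraquat. Libraries were near equal in depth, and 3 reads in a gene of 1 kb, the floor used for absence, correspond to 0.103 to 0.107 RPKM. Of 77 genes named by rule, 76 have a reference position and 8 of these overlap another annotated gene (AttC, CG13044, CG3088, CG32444, Jhbp5, fit, tobi and yellow-g), so part of their reads may belong to the neighbour. Near-identical gene copies lose reads when only unique ones are counted, so values of multigene families are uncertain on the absolute scale.

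The values were used as deposited. Differences are of log2(RPKM + 1), which understates changes of genes near 1 RPKM. With 1 library per group there was no test across replicates: a gene was called higher or lower at an absolute difference of at least 1, with RPKM of at least 1 in at least 1 library compared. Comparisons were paraquat against control in each genotype, mutant against wild type in each condition, the difference of the paraquat responses, and the genes shared by pairs of differences with no library in common, set beside the overlap of independent lists. Counting intervals at 95% are exact Clopper-Pearson intervals of the share of reads in 1 of 2 libraries, converted to a fold. They cover counting error only and say nothing of differences between flies.

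The comparisons, the size rule, the rule for named genes and 33 gene lists were set before the data were examined. Named genes are the 10 furthest higher and 10 furthest lower in each comparison with RPKM of at least 5, the 8 on each side for the difference of responses, the 10 on each side of each shared set, Kdm5, and up to 4 members of a list by size of difference. Neighbours of Kdm5, mitochondrial transcripts and a few list members outside these were chosen after their values were seen. A list's median was placed among 10000 random lists of the same size, drawn from 20 bins of mean expression, and a list was said to stand apart at or below percentile 2.5 or at or above 97.5. Random lists ignore that genes of a real list move together, so a percentile describes a list's place and is not a test. Of the lists, male accessory gland and testis genes had 0 members at 1 RPKM. The alternatives were pseudocounts of 0.1 and 5, no minimum or a minimum RPKM of 5, median-ratio and upper-quartile scaling and unmatched random lists. Values not divided by length, totals without the mitochondrial large ribosomal RNA and other baseline libraries were added after the data were seen.

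The size rule was checked on simulated Poisson counts with 200 genes changed by a known fold. These counts carry counting noise only, so the rates below say nothing of differences between flies. With no gene changed, counting noise put 0 genes past the rule in each comparison. In the runs with changed genes it put 1 unchanged gene past it in the wild type paraquat comparison (4-fold run), 2 and 1 between genotypes in control (2-fold and 4-fold runs) and 0 in the others. Of 4-fold changes 100% were found in each, on 8260, 8227, 8212 and 8334 genes. Of 2-fold changes, which lie on the rule itself, 18.5% were found in the wild type paraquat comparison on 8266 genes, 14.0% in the mutant one on 8242, 17.5% between genotypes in control on 8206 and 19.5% under paraquat on 8347. Calculations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.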

Results

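RNA from whole adult female Drosophila melanogaster aged 1 to 3 days was sequenced in a design that crossed genotype with oxidative stress. Wild type flies were w1118, and mutant flies carried the allele pair K6801/10424 of kdm5, the gene for a histone lysine demethylase that acts on chromatin. Flies of each genotype fed for 6 hours on 5% sucrose (control) or on 5% sucrose with 20 mM paraquat, a herbicide that cycles electrons inside cells and generates superoxide. Each of the 4 groups had 1 library, made from poly-A RNA of flies extracted in groups of 5. The libraries held 27.9 M uniquely mapped reads in the wild type control, 28.9 M in wild type with paraquat, 28.3 M in the mutant control and 29.1 M in the mutant with paraquat (M, 1e6). With 1 library per group no difference below has a replicate check and no p-value is given. A gene is called higher or lower when log2(RPKM + 1) differed by at least 1 and RPKM reached 1 in at least 1 library compared. Folds are ratios of RPKM, and the 95% intervals after them cover counting error only.

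Kdm5 (FBgn0031759; chromosome 2L, 5989400 to 5999501 in the BDGP6 annotation, minus strand) had 43.4 RPKM in the wild type control and 22.5 in wild type with paraquat, against 2.06 and 2.03 in the mutant libraries. The mutant level was 21.0-fold lower (19.4 to 22.9) in control flies and 11-fold lower (10.2 to 12) in paraquat flies. The mutant libraries still held 586 and 594 Kdm5 reads, which covered 61.2% and 57.4% of the gene length, against 79.1% and 78.0% in wild type. Of the nearest annotated genes, eIF4A, ifc and Tsp26A differed between the genotypes in control flies by −0.08, −0.20 and −0.20 on the log2 scale and under paraquat by −0.07, 0.18 and −0.71, and Gal by 1.75 and 0.06.

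The comparison of wild type flies with and without paraquat asked how an intact fly responds to oxidative stress. Of glutathione S-transferases, which join glutathione to reactive compounds, 18 of 35 measured members were higher with paraquat and 1 was lower, with a median difference of 1.03. GstD5 was at 3.08 RPKM in control and 49.6 in paraquat flies (16.1-fold, 12.3 to 21.5), GstD4 at 0.544 and 13.7, GstD2 at 20.8 and 158 and GstD3 at 4.89 and 41.2. All 5 metallothioneins, which bind metal ions, were higher, with a median of 2.39 and MtnD at 1.79 and 28.4 RPKM. Median RPKM of the glutathione S-transferases was 10.5 and 25.2 in wild type control and paraquat flies, and 16.1 and 21.3 in the mutant. That of the metallothioneins was 17.4 and 95.2, and 71.8 and 151. The wild type control was lowest for both lists, so the size of these rises cannot be told apart from a difference that belongs to that library. Eggshell transcripts went the other way: 7 of 14 were lower and 0 higher, and yellow-g2 was at 45.2 and 0.186 RPKM, the latter from 8 reads (243-fold lower, 123 to 564).

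Part of the other detoxification enzymes were higher as well. Among cytochrome P450s, oxidases of foreign compounds, 15 of 54 were higher, 2 lower and 37 neither (median 0.51), with Cyp9b2 at 13.6 and 203 RPKM (14.9-fold, 13.8 to 16.1), Cyp6d4 at 4.12 and 45.1, Cyp6a23 at 4.04 and 40.1 and Cyp28a5 at 7.89 and 66.6. UDP-glycosyltransferases, which attach sugars to foreign compounds, had 7 of 27 members higher, 0 lower and 20 neither (median 0.75). Median RPKM of the P450 list was 3.40 and 5.81 in wild type control and paraquat flies, and 7.27 and 7.57 in the mutant. That of the UDP-glycosyltransferase list was 3.73 and 8.27, and 5.81 and 5.99. The wild type control was lowest for both lists, so these rises cannot be told apart from a difference that belongs to that library. Ugt37A3 was 35.4-fold higher (29.5 to 42.9) and Ugt37A2 was 20.0-fold higher (17.4 to 23.1). The stress genes Gadd45 (7.78 and 32.0 RPKM) and Xrp1 (29.1 and 99.3) and the cell death inducer rpr (1.67 and 6.91) were higher, within a list of 13 JNK, cell death and DNA damage genes (median 0.46) in which Irbp was lower (29.3 and 11.7) and 9 were neither. Lactate dehydrogenase, Ldh, was at 4.41 and 42.4 RPKM. The classical antioxidant enzymes, such as superoxide dismutases and catalase, had a median of 0.02 over 14 members. Sod3 was lower (69.1 and 31.4 RPKM), and Cat, at 64.1 and 124, was just inside the size rule. Both lie near the rule and depend on scaling: the median gene differed by −0.29 and moved by 0.35 with median-ratio scaling. Heat shock proteins and co-chaperones were split, with Hsp23 (10.8 and 45.8) and stv higher and Hsp27 (447 and 134) and Hsp26 (379 and 134) lower.

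Transcripts of the mitochondrial genome, examined as a set after mt:ND3, mt:ND2, mt:ND5 and mt:srRNA came up among the 10 furthest higher genes, moved by unequal amounts. Of 12 with at least 100 reads in both libraries 10 were higher, with a median of 2.40. mt:ND2 and mt:ND5, subunits of respiratory complex I, were at 5.30 and 107 and at 47.5 and 640 RPKM, and the small ribosomal RNA mt:srRNA was at 4.74 and 85.1. mt:ND3, with 53 control reads, was 87.5-fold higher (66.7 to 117). The large ribosomal RNA mt:lrRNA, which took 9.12% of reads in the control and 11.5% with paraquat, differed by 0.34. The 43 nuclear genes of the respiratory chain had a median of 0.65 and quartiles of 0.56 and 0.78, with 0 past the size rule. That count depends on scaling, since median-ratio and upper-quartile scaling raised the median gene by 0.35 and 0.45.

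Genes of egg production were on the lower side. Chorion genes, which encode the outer eggshell, included Cp15 at 2362 and 212 RPKM (11.1-fold lower, 10.8 to 11.5) and Cp19 at 865 and 78.1, and yellow-g was 38.7-fold lower (29.1 to 52.7). CG13114, CG15570 and CG15571 were left with 7, 11 and 10 reads after paraquat, from 1855, 2368 and 496. The mucin gene Muc4B, CG4009 and CG13084 were also among the 10 furthest lower. The yolk protein genes Yp1, Yp2 and Yp3 had differences of −1.13, −0.91 and −1.25. Of 16 female germline genes 9 were lower and 0 higher (median −1.11), among them png, krimp, bcd and bam, each between −1.40 and −1.51. With a median this near the rule the count depends on scaling: over all genes, median-ratio scaling cut those lower from 879 to 227.

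Markers of body tissues moved in the same library pair. Muscle genes were higher in 13 of 15 cases (median 1.46; fln 113 and 508 RPKM, Act88F 307 and 1308), starch and sugar digesting enzymes in 11 of 15 (median 1.57; tobi 3.69 and 36.6, Mal-A7 18.6 and 88.2), larval serum and larval fat body genes in 6 of 6 (median 1.90; Fbp1 1.93 and 17.5) and cuticle proteins in 15 of 35 (median 0.86; Cpr62Bc 14 and 79.7). Photoreceptor and neuron markers had medians of 0.47 and 0.75 with 0 members past the size rule. The neuron count depends on scaling: its quartiles were 0.73 and 0.82, and median-ratio scaling raised the median gene by 0.35. The 1 added to RPKM also shrinks the neuron differences, since the list's median RPKM was 2.24 in the control and 4.49 with paraquat. The wild type control stood apart from the other libraries: its differences from them had an SD of 0.72 to 0.75 across genes, against 0.28 to 0.59 among the other 3.

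In all, 439 genes were higher and 879 lower of 8429, so that 33.3% of those past the size rule were higher. The median gene differed by −0.29, which median-ratio and upper-quartile scaling shifted by 0.35 and 0.45, and 81.3% and 89.6% of genes past the rule were then higher. Counts of list members past the rule in this comparison carry the same dependence on scaling. Of 32 lists, 14 lay in the top 2.5% of 10000 random lists matched on expression and 4 in the bottom 2.5%. Random lists ignore that genes of a real list move together, so these totals have no chance value to be set against. The glutathione S-transferase, P450, UDP-glycosyltransferase, metallothionein, muscle and carbohydrate digestion lists were all at percentile 100. Set against the mutant control as the baseline, an alternative chosen after seeing the data that also crosses genotypes, wild type flies with paraquat had 274 genes higher and 265 lower.

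**Figure D1:**
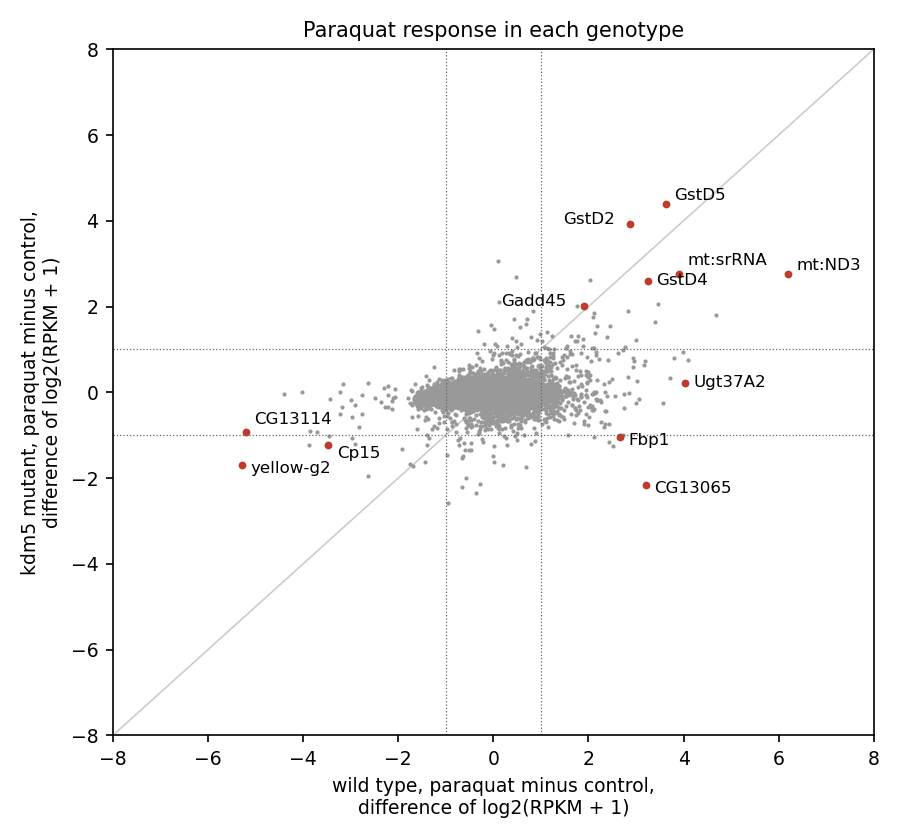
Difference of log2(RPKM + 1) between paraquat and control in wild type (horizontal) and in the kdm5 mutant (vertical), 1 point per gene, with named genes in red and the size rule of 1 as dotted lines. GstD5 and GstD2 lie high on both axes, while yellow-g2, at −5.28 and −1.69, and Ugt37A2, at 4.03 and 0.22, lie further out in wild type than in the mutant.

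The comparison of mutant flies with and without paraquat asked how flies with little Kdm5 respond to the same stress. Of the glutathione S-transferases 9 of 35 were higher and 0 lower (median 0.39), with GstD5 at 1.90 and 59.5 RPKM (31.3-fold, 22.4 to 45.2), GstD2 at 7.94 and 135 (17.0-fold, 14.5 to 20.0), GstD4 at 0.88 and 10.4 and GstD3 at 31.1 and 119. Of the 5 metallothioneins 4 were higher, MtnD most (29.6 and 94.4 RPKM), with a median of 1.06. Genes of the antimicrobial peptide list were lower in 3 of 13 cases and higher in 0 (median −0.29): the attacin AttC was at 55.0 and 11.8 RPKM, the diptericin DptA at 49.0 and 18.9, and CecC at 2.95 and 0.831.

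Single members of other stress lists were also higher in the mutant with paraquat. Gadd45 was at 5.53 and 25.4 RPKM, Thor, a brake on translation downstream of insulin signalling, at 98.5 and 299, Ldh at 9.96 and 24.5, Hsp68 at 6.49 and 18.1 and Ugt37A3 at 6.11 and 23.6. Cytochrome P450s had 2 members higher, 1 lower and a median of −0.02 that turned to 0.02 with median-ratio scaling. CG14205 (0.818 and 14.2), CG15043 (15.8 and 108) and CG13324 (25.7 and 113) were past the rule in the mutant and differed by 0.10, 0.47 and 0.13 in wild type. Among mitochondrial transcripts mt:ND3 (18.9 and 133), mt:srRNA (4.05 and 33.2) and mt:ND6 (2.22 and 5.50) were higher, and the median over the 12 chosen by their reads in wild type was 0.63.

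On the lower side, 5 of 14 eggshell genes were lower (median −0.67), with Fcp3C, a follicle cell protein, at 24.6 and 4.04 RPKM and yellow-g2 at 92.7 and 28.0. The yolk list had a median of −0.71 with 0 past the rule. Of 6 Turandot and JAK-STAT genes TotC, TotM and TotA were lower (−1.47, −1.35 and −1.08) and 3 were neither. Other genes among the furthest lower were the odorant-binding protein gene Obp19c (41.4 and 6.06 RPKM), the desaturase Fad2 (25.4 and 4.74), Jhbp5, Pebp1 and CG3999. Muscle, carbohydrate digestion and female germline lists had medians of −0.05, −0.05 and −0.08. Gut serine proteases had a median of −0.28, with 2 of 25 lower and 0 higher. Larval serum genes had a median of −0.69.

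In the mutant, 59 genes were higher and 50 lower of 8288, 109 in all against 1318 in wild type. These depend on the pseudocount: 0.1 gave 101 higher and 88 lower in the mutant and 755 and 1119 in wild type, and 5 gave 37 and 28 and 226 and 363. The median gene differed by −0.05. Of 32 lists, 7 stood in the top 2.5% of matched random lists and 10 in the bottom 2.5%.

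Genes past the rule in both genotypes, whose differences share no library, numbered 37 higher, where independent lists would share 3.01, and 13 lower, where they would share 5.10. The value for independent lists takes every gene as equally likely to pass the rule. Genes that vary between any pair of libraries can raise the overlap above it without a shared response. The 37 included GstD5, GstD2, GstD4, GstD3, Gadd45, mt:ND3, mt:srRNA, CG16898, CG2065 and CG13215. The 13 included yellow-g2, yellow-g, Cp15, DptA, CG14834, PGRP-SB1, a secreted peptidoglycan recognition protein, and fit, a fat body gene that was 7.61-fold lower (5.75 to 10.3) in wild type and 4.18-fold lower (3.50 to 5.01) in the mutant. Of the mutant's 59 higher genes 94.9% had the same sign in wild type, with a median of 1.53 there. Of its 50 lower genes 64% had the same sign, with a median of −0.50 in wild type, where the median of all genes was −0.29. Opposite directions were seen for 7 genes that were higher in wild type and lower in the mutant and for 0 the other way. In the reverse direction, the 439 genes higher in wild type had a median of 0.00 in the mutant. Across 8611 genes, which are not independent replicates, the responses had a Pearson correlation of 0.21 and a Spearman correlation of 0.11.

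**Figure D2:**
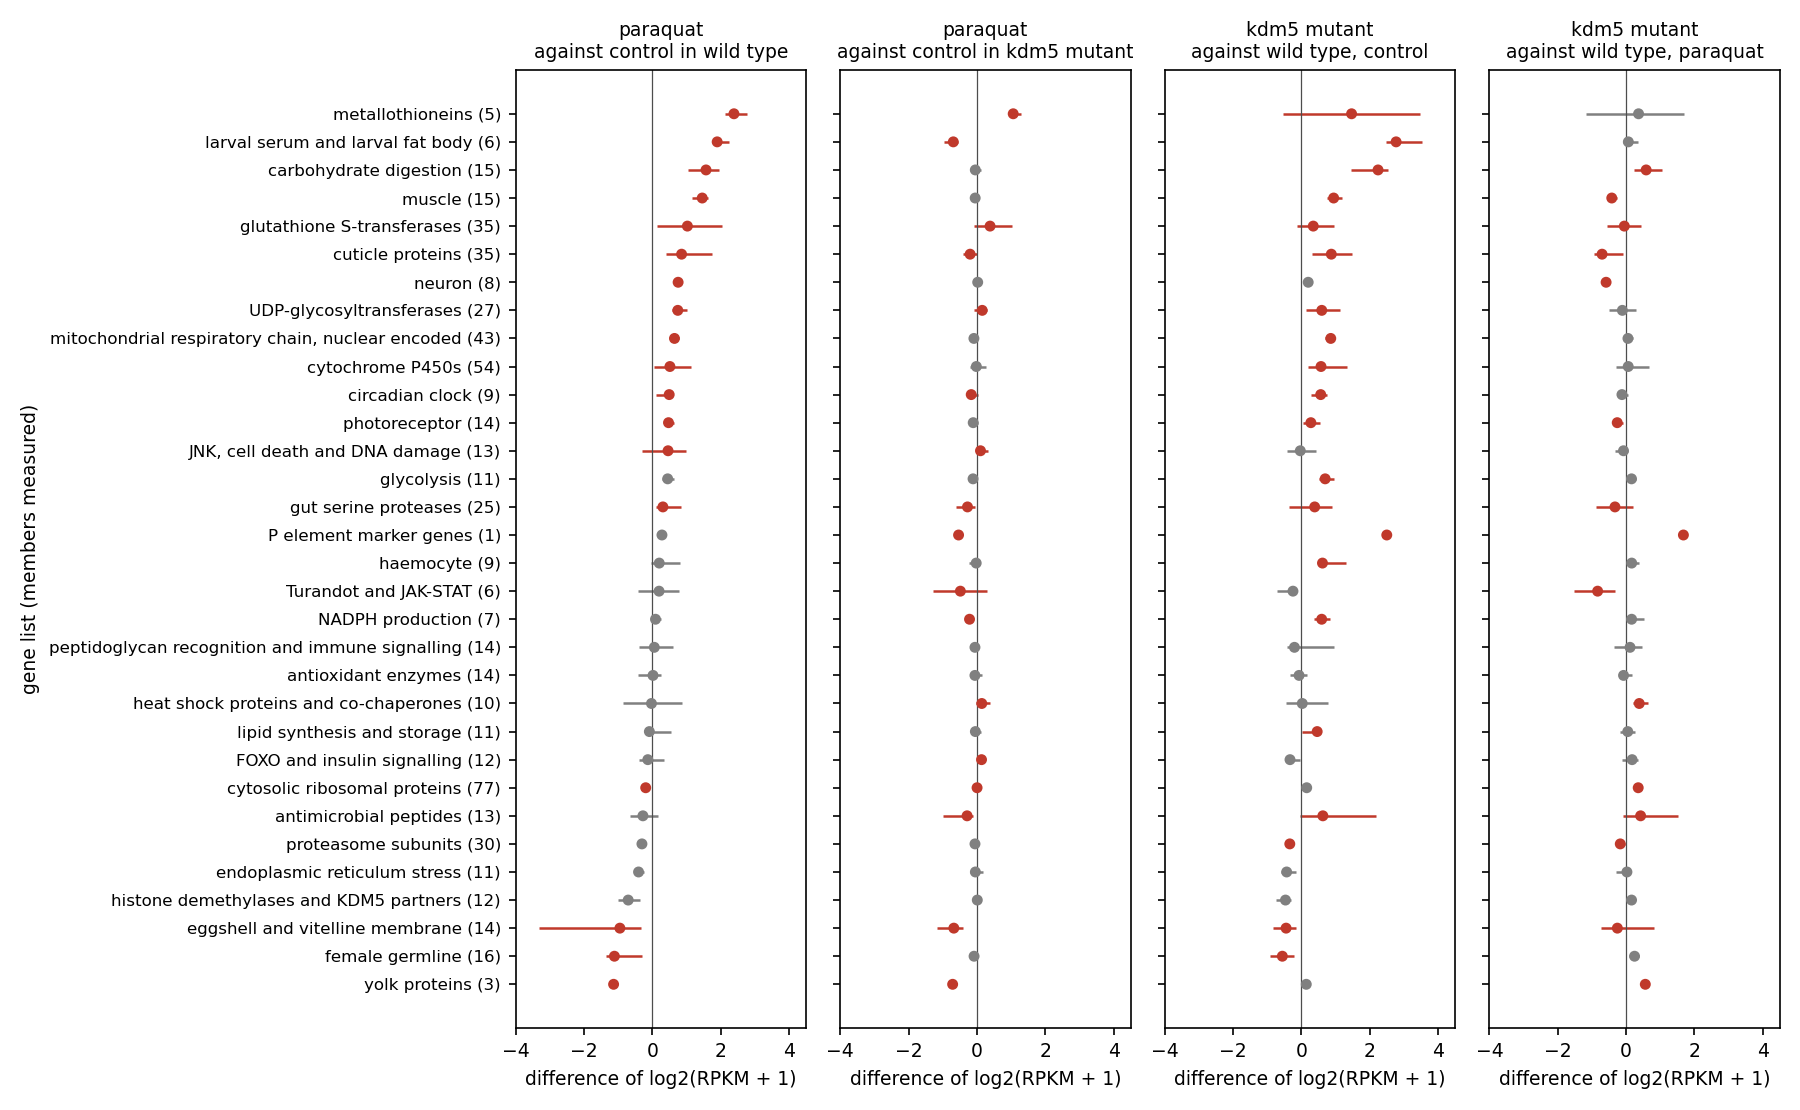
Median difference of log2(RPKM + 1) of each gene list (point) with its quartiles (line) in the 4 comparisons, with the number of measured members in brackets; red lists lie in the top or bottom 2.5% of matched random lists. Metallothioneins, at 2.39 and 1.06, and glutathione S-transferases, at 1.03 and 0.39, lie to the right in both paraquat panels, while muscle, at 1.46 and −0.05, does so in wild type.

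The comparison of the genotypes in control flies asked what loss of Kdm5 does without stress. Enzymes of starch and sugar digestion were higher in the mutant in 14 of 15 cases (median 2.24), led by tobi, an alpha-glucosidase gene that responds to insulin and diet, at 3.69 and 277 RPKM (75-fold, 65.7 to 85.9), with Mal-A3, Mal-A6 and Mal-A7 at 2.73, 2.60 and 2.60 on the log2 scale. All 6 larval serum and larval fat body genes were higher (median 2.77), with Fbp1 at 1.93 and 48.3 RPKM and Lsp2 at 10.6 and 149. Antimicrobial peptide genes were higher in 6 of 13 cases and lower in 1 (median 0.63): BomBc1 (2.69 and 37.9), AttC (6.95 and 55.0) and DptA (8.87 and 49.0) were higher and AttD (12.3 and 0.604) was lower. On the lower side stood dhd, a thioredoxin of the female germline, at 2014 and 114 RPKM (17.6-fold lower, 16.9 to 18.3).

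Some detoxification genes were higher in the mutant controls too. This held for 17 of 54 cytochrome P450s (median 0.57; Cyp6a20 1.87 and 26.9 RPKM, Cyp4e3 13.9 and 87.4), 10 of 27 UDP-glycosyltransferases (median 0.59; Ugt35C1 3.29 and 36.7), and 9 of 35 glutathione S-transferases (median 0.35; GstD3 4.89 and 31.1, GstD1 72.0 and 289). GstD2 (20.8 and 7.94), Ugt36E1 (22.1 and 2.19) and Cyp6a19 (133 and 37.8) were lower, and the other members were neither. Of 5 metallothioneins (median 1.47) MtnE (3.70 and 71.8), MtnD (1.79 and 29.6) and MtnC (58.4 and 163) were higher, while MtnB and MtnA differed by −0.67 and −0.53. The nuclear respiratory chain list had a median of 0.86, with 6 of 43 higher (SdhB 104 and 253, ATPsynbeta 482 and 1142), and glycolytic genes had a median of 0.69, with Gapdh1 at 517 and 1387.

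Tissue markers moved along with these groups. Muscle genes were higher in 7 of 15 cases (median 0.94; Act88F 307 and 1453 RPKM), cuticle proteins in 14 of 35 with 2 lower (median 0.87), and haemocyte genes in 3 of 9 (median 0.62; NimC1 1.06 and 4.72). Female germline genes had a median of −0.56, with png, bam and bcd lower, and eggshell genes a median of −0.45, with 3 of 14 lower (Cp18 1049 and 179 RPKM, Cp15 2362 and 540, and Cp16) and yellow-g2 higher (45.2 and 92.7). Each of these values rests on the same wild type control library as the paraquat comparison in wild type, so the comparisons are not independent of each other.

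Of 8364 genes 548 were higher and 481 lower in mutant controls, 53.3% of those past the rule being higher. The median gene differed by −0.19. Median-ratio and upper-quartile scaling shifted this by 0.22 and 0.26, with 77.3% and 79.9% then higher. With wild type paraquat flies as the baseline, also chosen after seeing the data, 265 genes were higher and 274 lower.

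The comparison of the genotypes under paraquat asked what loss of Kdm5 does in stressed flies. Antimicrobial peptide genes were again higher in the mutant, 5 of 13 with 1 lower (median 0.43): DptA was at 1.6 and 18.9 RPKM, BomBc1 at 3.97 and 33.7 and BomS2 at 76.7 and 266, while AttD was at 7.52 and 0.462. Of 6 Turandot and JAK-STAT genes 3 were lower and 0 higher (median −0.83), with TotC at 13.0 and 0.522 RPKM. Starch and sugar digesting enzymes were higher in 4 of 15 cases (median 0.59), with tobi at 36.6 and 231 RPKM. Gut serine proteases went the other way, with 3 of 25 higher, 5 lower and a median of −0.32. Eggshell genes divided, with yellow-g2 (0.186 and 28.0) and yellow-g (0.575 and 17) higher and Fcp3C (23.5 and 4.04) lower.

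Yolk protein genes had a median of 0.57 and the ribosomal protein genes a median of 0.36, both in the top 2.5% of matched random lists. The glutathione S-transferase and P450 lists had medians of −0.05 and 0.06, the latter turning to −0.03 with median-ratio scaling. GstE8 was at 14 and 66.1 RPKM and Cyp6a20 at 7.58 and 34.9. The 12 mitochondrial transcripts chosen by their reads in wild type were lower in 6 cases (median −1.02), with mt:ND2 9.44-fold lower (8.44 to 10.6). Cuticle proteins had 7 of 35 lower and 3 higher (median −0.70), and muscle and neuron lists had medians of −0.42 and −0.58. Of 8487 genes 195 were higher and 229 lower, 46.0% of them higher. Upper-quartile scaling gave 35.8%, and shifted the median of 0.08 by −0.13.

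Genes that differed between genotypes in the same direction in both conditions, from separate libraries, numbered 135 higher and 87 lower, where independent lists would share 12.4 and 12.8. These values again take every gene as equally likely to pass the rule. lncRNA:CR40469 was at 0.836 and 1.45 RPKM in the wild type libraries and at 334 and 336 in the mutant ones. CG7542 was at 2.11 and 1.41 against 146 and 100.02, and the serine protease gene Ser12 had 2 reads and no row, taken as 0 reads, against 616 and 606. Drsl4, a drosomycin-like gene, CG33346, CG16758, CG32444 and CG12780 were also higher in both. On the lower side, lncRNA:CR32368 was at 265 and 251 RPKM in wild type against 6.63 and 6.46 in the mutant. The lysozyme gene LysX was at 81.9 and 57.1 against 2.32 and 4.15, CG31041 at 45.3 and 57.6 against 2.03 and 1.73, and CG12934 at 16.0 and 20.5 against 0.30 and 0.219. CG33109, CG10725, Nazo and Acbp3, an acyl-CoA-binding protein gene, were lower in both as well. Opposite directions were seen for 24 genes that were higher in control and lower under paraquat and for 3 the other way. Across 8611 genes the Pearson correlation was 0.32 and the Spearman correlation 0.07.

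**Figure D3:**
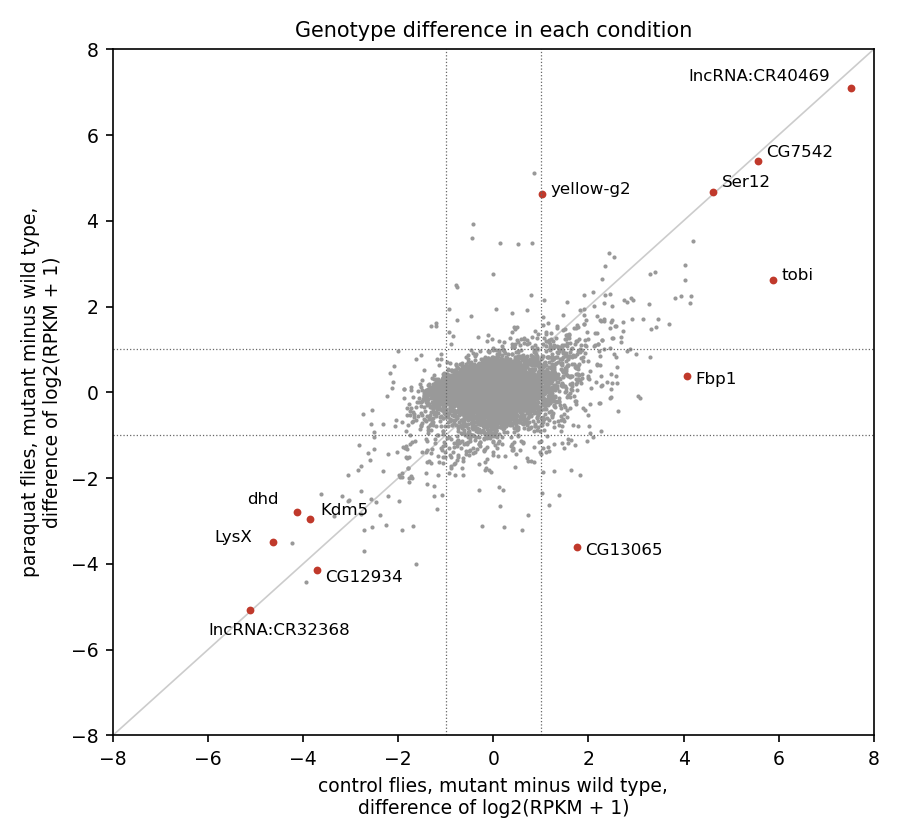
Difference of log2(RPKM + 1) between mutant and wild type in control flies (horizontal) and paraquat flies (vertical), 1 point per gene, with named genes in red and the size rule of 1 as dotted lines. lncRNA:CR40469 (7.51 and 7.10), CG7542 (5.56 and 5.39) and lncRNA:CR32368 (−5.12 and −5.08) lie near the diagonal, and CG13065 (1.76 and −3.60) lies far from it.

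The difference between the responses, mutant minus wild type, asked where the genotypes responded unlike each other, and with 1 library per group nothing is left to estimate its error. Starch and sugar digesting enzymes had a median of −1.41, metallothioneins −1.11, UDP-glycosyltransferases −0.65 and P450s −0.44: their paraquat differences were smaller or lower in the mutant. The glutathione S-transferases had −0.37, with GstD2 at 1.06 and GstD5 at 0.75 on the other side. Muscle genes (−1.42), larval serum genes (−2.58), cuticle proteins (−1.11) and female germline genes (0.97) moved with them. All these values rest on the wild type control, in which 14 of 15 starch and sugar digesting enzymes were lowest. A weaker response in the mutant therefore cannot be told apart from a difference that belongs to that library. CG15571, CG13114 and CG15570 were highest, at 4.36, 4.26 and 4.03, and CG13065 lowest, at −5.36. By size, 720 genes were higher and 532 lower of 8611, 57.5% higher, against 13.5% and 7.78% after median-ratio and upper-quartile scaling, which moved the median of 0.25 by −0.31 and −0.39.

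**Figure D4:**
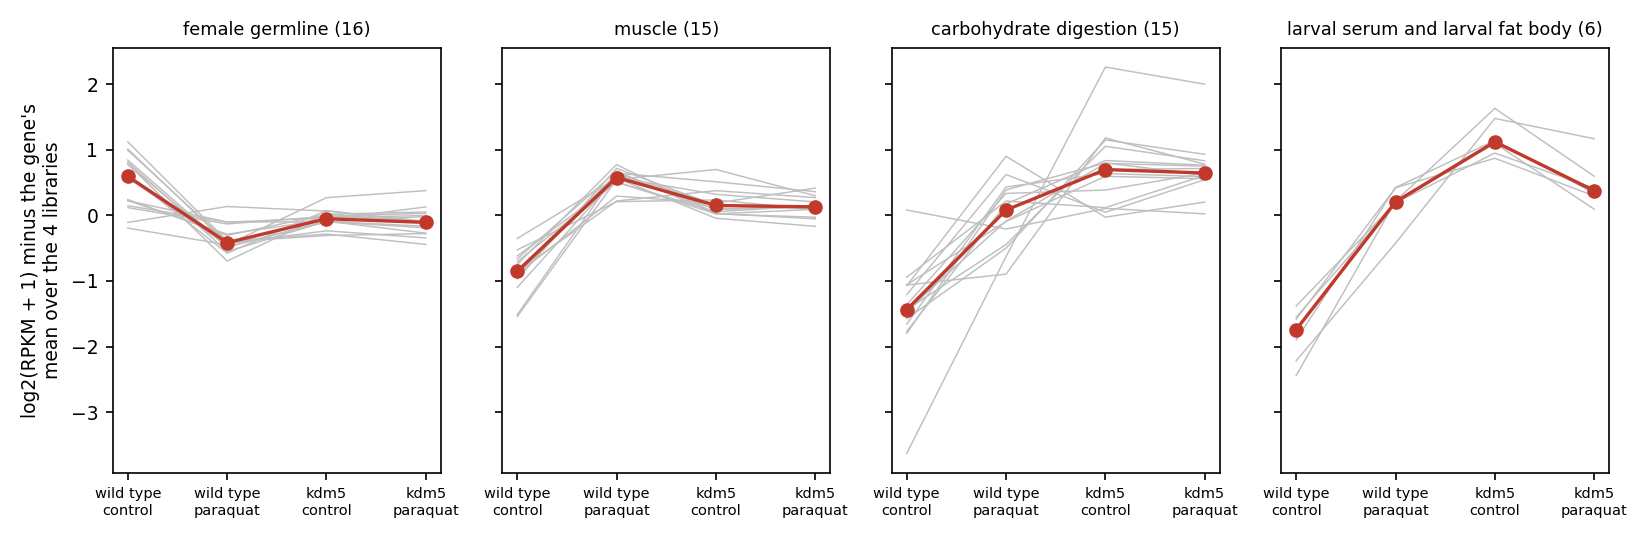
log2(RPKM + 1) minus the gene's mean over the 4 libraries, for the measured genes of 4 lists (grey lines) and their median (red). All 15 muscle genes and all 6 larval serum genes are lowest in the wild type control, and 14 of 16 female germline genes are highest there.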

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

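The tests below on ovary RNA, on fly age and on mitochondrial RNA were chosen after the values were seen; those on scaling and on chromosome positions were set before, and the check on autosomes alone was added after the share on chromosome 2 was seen. Several results had opposite signs in groups under the same contrast, a difference that was not tested because each group has 1 library. Under paraquat, wild type and mutant differences on the log2 scale were 3.20 and −2.16 for CG13065, 2.42 and −1.16 for CG5172, 2.73 and −1.004 for CG8736, 2.66 and −1.03 for Fbp1, 2.52 and −1.26 for the gut protease gene Jon25Bii, and 1.90 and −0.69 for the median of larval serum and larval fat body genes. Between genotypes, control and paraquat differences were 1.76 and −3.60 for CG13065, 1.81 and −1.92 for CG8736, 1.38 and −2.40 for Jon25Bii, 1.15 and −1.28 for Pebp1, 1.17 and −2.63 for Ugt37A2, 1.03 and −1.85 for Ugt37A3, 1.64 and −1.81 for mt:ND3, 1.03 and −2.35 for mt:ND5, and 0.87 and −0.70 for the median of cuticle proteins.

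Between paraquat and control flies 1318 genes differed past the size rule in wild type and 109 in the mutant. Scaling by total reads is argued against as the whole cause, since after median-ratio scaling the ratio of these totals was 11.53 (1211 against 105). A larger share of ovary RNA in the wild type control, as the only change, would raise every other tissue's markers alike in the paraquat library. The lower quartile of muscle lay 0.535 above the upper quartile of photoreceptor genes on the log2 scale, so these lists did not rise alike. Both lists were picked for this after their values were seen, so the gap describes them and does not decide the question. A larger share of ovary RNA stays possible: in the wild type control 14 of 16 female germline genes were highest, and 15 of 15 muscle and 10 of 14 photoreceptor genes were lowest. Older flies in the wild type control, within the stated 1 to 3 days, stay possible: larval serum transcripts, which wane after eclosion, were lowest there in 6 of 6 cases, with a lower quartile of the gap of 1.755. That value cannot establish age, because the explanation came from the same values and the labels give 1 age range for all libraries. A weaker response to paraquat in flies with little Kdm5 also stays open, and the design cannot separate it from a difference that belongs to the wild type control library.

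Genes that differed between genotypes in the same direction in both conditions may follow from loss of Kdm5 or from other variants that the mutant chromosomes carry. Of 219 such genes with a position, Kdm5 itself left out, 47.49% lay on chromosome 2, where Kdm5 is, against 38.5% of all genes and at most 44.7% in the central 95% of random sets. The excess lay on arm 2R (29.7% against 20.7%), while 2L, which carries Kdm5, was at background (17.8% for both), and 3L was also raised (24.7% against 19.4%). On the autosomes alone the share was 50.7%, inside the random bound of 52.7%, and genes on the X were few (6.39% against 16.0%). Linkage to chromosome 2 therefore cannot be told apart from an effect of Kdm5 on autosomal genes, or from variants that the mutant flies carry on other chromosomes. A carried segment around Kdm5 is argued against for the set as a whole: 2.283% of the genes lay within 2 Mb of it, against 3.51% of all genes.

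Of 12 mitochondrial transcripts 10 were higher with paraquat in wild type. A single change in the amount of mitochondrial RNA would move them alike, but their differences had an interquartile range of 1.562 on the log2 scale, from 0.34 for mt:lrRNA to 4.10 for mt:ND2. Their poly-A tails and how well the poly-A selection caught them were not tested, and a response to paraquat stays open.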

How the results depend on the processing

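Other baselines, values not divided by length and totals without the mitochondrial large ribosomal RNA were chosen after seeing the data, and the other settings before. Pseudocount 0.1 gave 755 genes higher under paraquat in wild type, 101 higher and 88 lower in the mutant, 359 lower in mutant against wild type paraquat flies, 950 lower in the difference of responses, 67 higher and 25 lower shared by the genotypes, and 162 lower shared by the conditions. Pseudocount 5 gave, in the same order, 226 higher and 363 lower, 37 and 28, 91 and 113, 281 and 247, 24 higher, and 58 and 38, and 250 and 185 between genotypes in control. Median-ratio scaling gave 984 and 227 for paraquat in wild type, 238 lower in mutant controls, and 169 and 1081 for the difference of responses. Upper-quartile scaling gave 1196 and 139, 852 and 214, and 105 and 1245 for these. Values not divided by length gave 690 higher for paraquat in wild type and 913 lower for the difference of responses. With the mutant control as the baseline, wild type paraquat flies had 274 higher and 265 lower, and with wild type paraquat as the baseline mutant controls had 265 and 274. The ribosomal protein list turned from −0.19 to 0.188 and 0.291 for paraquat in wild type, and from 0.21 to −0.134 and −0.217 for the difference of responses, with median-ratio and upper-quartile scaling. The cause of each of these moves was not tested. The other 78 counts under an alternative stayed within 1.5 times the main one. Of values of named genes 812 stayed within 1.5 times and 140 moved further. Of list medians 1260 were counted as unchanged, 16 as moved and 4, those of the ribosomal protein list, as reversed. Unchanged does not mean equal here, since it includes small P450 medians that changed sign with median-ratio scaling. With unmatched random lists 15 of 160 list percentiles crossed the bound. Removing the trend with exonic length, tested as a cause of the wild type to mutant ratio of paraquat totals, left it at 11.11. Taking the highest of several rows per gene was not run, since no gene has several, and no library could be left out with 1 per group. Depth limits genes of few reads: yellow-g2 and CG13114 rest on 8 and 7 reads in wild type paraquat flies. No paired analysis was possible because each group has 1 library and no replicate numbers to pair.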

Other observations

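Genes that make NADPH had a median of 0.59 in mutant controls, with Taldo, a transaldolase, at 58.5 and 141 RPKM, and lipid synthesis and storage genes a median of 0.46, with 0 of 11 past the size rule. Under paraquat in wild type the glycerol phosphate dehydrogenase gene Gpdh1 (113 and 254 RPKM) and the lipid droplet gene Lsd-1 (18.8 and 41.3) were higher. Proteasome subunits had medians of −0.34 and −0.17 in mutant against wild type in control and paraquat flies, both at or below the 2.5th percentile, with 0 of 30 past the size rule. Endoplasmic reticulum stress genes had 0 of 11 past the rule in each of the 4 comparisons. Of the peptidoglycan recognition and immune signalling list, PGRP-SC2 was at 46.9 and 132 RPKM in wild type and mutant controls.

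Of 12 genes for other histone demethylases and for partners of Kdm5, HDAC1 (58.7 and 23.1 RPKM), Su(var)3-3 (23.6 and 9.62) and Kdm4A (33.5 and 14) were lower under paraquat in wild type, and the list median of −0.71 lay at percentile 9.05. These calls lie near the size rule and depend on scaling. The median gene of that comparison moved by 0.35 with median-ratio scaling, and the genes lower fell from 879 to 227. The clock gene cyc was lower in mutant controls, at 33.3 and 11.7 RPKM, while the circadian list had a median of 0.56. The xanthine dehydrogenase gene ry, which also serves as a marker in some P element vectors, was at 2.91 and 3.75 RPKM in wild type and at 21.1 and 14.2 in the mutant. RpS19b, a ribosomal protein paralog, was at 0.312 and 0.216 RPKM in wild type and 5.55 and 4.12 in the mutant. Wild type paraquat flies had the highest value of the 4 libraries for 11 of 15 muscle genes and 8 of 8 neuron genes.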
